A study of Mus musculus with 12 samples.

How the data were processed

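The series holds 12 RNA-seq samples of microglia, the resident macrophages of the brain, isolated from mouse midbrain and sorted by flow cytometry, per the labels' protocols. Control animals (WT) carried the conditional Ppargc1a allele, and deficient animals (KO) lacked Ppargc1a in microglia. Animals of each genotype received MPTP, a toxin that kills dopaminergic neurons, or PBS, and the labels place all samples 6 weeks after tamoxifen. The labels number 3 samples in each of the 4 groups. Nothing in the sources used here says whether samples of a group came from separate animals, so p-values measure only the spread between profiles, which may be technical.

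The authors deposited 1 table with 67355 rows and 12 columns, named by group and replicate number. CASAVA 1.5, Bowtie 0.12.7, TopHat and Cufflinks and the genome build mm9 are named in the submitters' processing notes, with no role or order. No header states the unit. The deposited values were taken as FPKM, fragment counts scaled by transcript length and by all mapped fragments, because Cufflinks writes that unit. They carry 2 decimals and sum to between 388861 and 434022 per column. The annotation, the filters and the definition of a row are not given in the sources used here. Read depth is unknown, so no counting interval is given. The reference at hand was of another build, so no coordinates are printed and it was used for gene symbols only. Row names are a gene symbol and a number. Rows were summed per symbol into 21125 genes, of which 20286 matched a reference symbol. 1 cell held text in place of a number, and its row was left out of the sums.

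The columns were compared with one another before any group was compared. For 6 of the 12 columns, a fixed arithmetic relation to other columns gave the deposited value to rounding in nearly every row. A row counted as following its relation when it lay within 0.0101 FPKM for the 2 columns that are multiples of 1 other column, and within 0.00995 FPKM for the 4 that rest on a mean. These limits are what rounding of the deposited values to 2 decimals allows. Such columns carry no error of their own, and the table therefore holds 6 separate profiles: WT PBS 1, WT PBS 2, WT MPTP 1, KO PBS 1, KO PBS 2 and KO MPTP 2. The profile of KO PBS 2 also stands, multiplied by 1.02, under KO MPTP 1. The table does not show which treatment that profile had.

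Before the data were examined, the design fixed limma with a mean-variance trend on log2(FPKM + 1), 1 mean per group and 12 libraries in 1 fit. That fit treats computed columns as replicates, so it is given as an alternative and not as the result. The fit reported here was chosen after the columns had been compared and after trial fits had been seen. It used 5 separate profiles, each counted once, and left out the profile under 2 group labels. WT PBS had 2 profiles and every other group had 1. The fit had 1 residual degree of freedom, from the WT PBS pair, and 9.01 prior degrees of freedom. The single profiles were assumed to vary like that pair, and p-values rest on this assumption. The alternatives that count the left-out profile as KO PBS or as KO MPTP were also fitted. As KO MPTP it was entered once with the values of KO PBS 2 and once with those of KO MPTP 1, which differ beyond the factor only in the rows off that relation. limma 3.58.1 in R 4.3.3 was used with Benjamini-Hochberg adjustment and a threshold of 0.05 within each comparison. Genes needed at least 1 FPKM in at least 3 of the 6 separate profiles, which left 10634 genes. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

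Named genes follow a rule fixed before the data were examined: per comparison, the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, and 5 of each for the interaction. Predicted genes, small RNAs and olfactory receptors were counted but not named. Up to 4 called members of each of 32 fixed gene lists were added, or the 2 members of highest mean value where none was called. Ppargc1a was given in every column. The planned set test, camera, was not used, because with single profiles its p-value would treat genes as replicates. Instead a list's median log2 fold change was placed among 10000 random lists of the same size matched on mean expression. That percentile describes these profiles only. The same percentile was computed between the 2 WT PBS profiles as a background with no treatment or genotype difference. Members called when adjusted over the list alone were counted as well.

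The procedure was tested on simulated data. In 20 draws of 10634 genes for MPTP in WT, with 200 changed genes, the fit of 5 profiles recovered 81.8% of changes of 0.5 on the log2 scale and 99.8% of changes of 1, with 3.1 false calls per draw. In 20 draws with no effect, it called 0 genes in each comparison. The spread in these draws was taken from the WT PBS pair. Alternatives were other pseudocounts (0.1 and 0.5), no filter, a filter at 5 FPKM, quantile normalization, rescaling by trimmed means of M values (TMM, computed on the deposited values), no variance trend, a fit on only the groups compared, a threshold of 0.1, rows tested singly, profiles left out in turn, and genes with a row off the relations left out. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 was used for the column comparisons and Fisher's exact tests.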

Results

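RNA-seq was used to measure gene expression in microglia sorted from mouse midbrain, in control animals (WT) and in animals with a microglial deficiency of Ppargc1a (KO), after MPTP or PBS. Ppargc1a encodes a transcriptional coactivator of mitochondrial biogenesis and oxidative metabolism, and MPTP is a toxin of dopaminergic neurons. The labels give 4 groups of 3 samples. The deposited values, taken as FPKM, summed to between 388861 and 434022 per column, and the 20 highest genes held between 17.1% and 18.3% of the total. The read depth of each sample is unknown.

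The 12 columns did not hold 12 separate measurements. In each group, column 3 equalled 0.1 plus 0.99 times the mean of columns 1 and 2, to rounding, with 1 exception among 67355 rows in WT PBS 3 and 0 in the other groups. WT MPTP 2 equalled 1.02 times WT MPTP 1 in all but 28 rows. KO MPTP 1 equalled 1.02 times KO PBS 2, a column of the other treatment, in all but 46 rows. Among rows of at least 10 FPKM, 99.66% of WT MPTP 2 and 99.45% of KO MPTP 1 followed the relation within rounding. Between separate columns, at most 0.82% of such rows lay within rounding of the median ratio of the pair, the only factor tried. The lowest value in every column 3 was 0.1, and none of those columns held a row at 0, whereas the other columns held between 14648 and 16674 such rows. The table therefore held 6 separate profiles, and 1 of them stood under both KO PBS and KO MPTP.

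**Figure D1:**
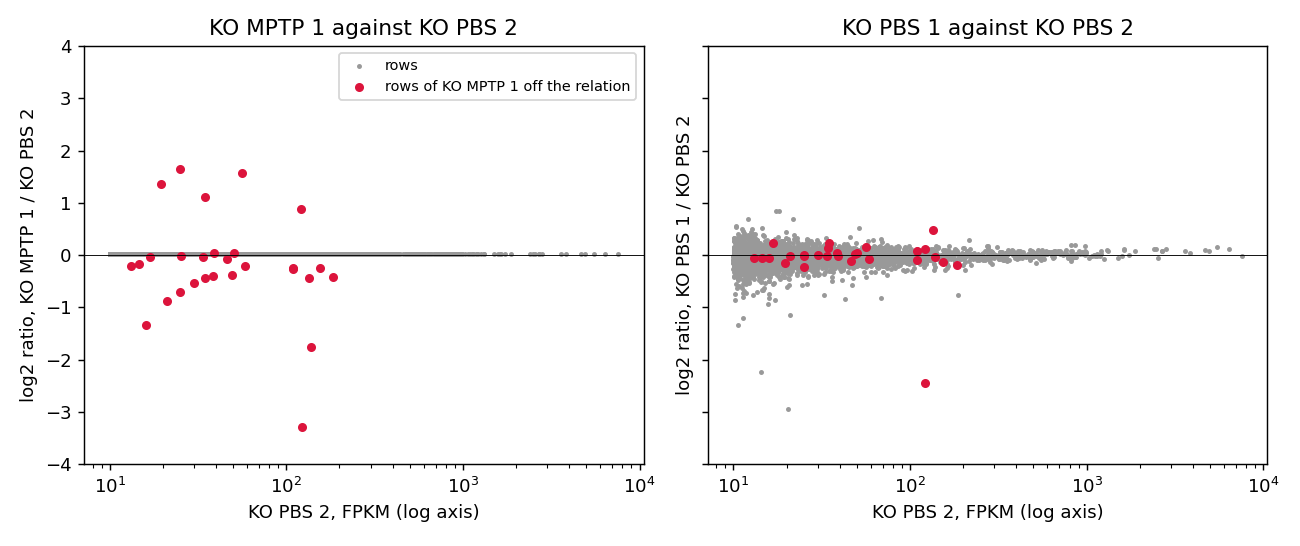
Log2 ratio of KO MPTP 1 to KO PBS 2 (left) and of KO PBS 1 to KO PBS 2 (right) against the FPKM of KO PBS 2 on a log axis, for rows of at least 10 FPKM, with each grey point 1 row and red points the rows of KO MPTP 1 off the relation. On the left 99.45% of the rows lie on a line within rounding, and on the right the rows scatter.

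The rows that departed from the relations numbered 49, in 42 genes. Taking the largest departure of each row, the median was 2.19 FPKM and the lowest 0.123 FPKM. Of these rows, 25 were off in both WT MPTP 2 and KO MPTP 1, 21 only in KO MPTP 1 and 3 only in WT MPTP 2. The genes included Ppargc1a, the inflammatory genes Tnf, Il1b, Nos2 and Ccl2, the antioxidant genes Sod1, Sod2 and Gpx1, the mitochondrial regulators Tfam and Nrf1, the respiratory chain genes Atp5a1, Cox6c, Cox7b, Ndufa2 and Ndufs8, and the glucose transporter gene Slc2a1. Of the 42 genes, 29 (69.0%) belonged to gene lists fixed before the data were examined, against 3.37% of the other genes (Fisher's exact test, two-sided p = 5.73e-33). In KO MPTP 1, 36 of the 46 departing rows lay nearer to KO MPTP 2 than to KO PBS 2. These 42 genes are called genes off the relations below. A number of the departures lay close to whole numbers, such as 100.003 FPKM for S100a6, 99.994 for Sod1, 50.005 for Gpx1, 39.996 for Nos2, 28.001 for Atp5a1 and 5.007 for Tnf. Others did not, such as 37.797 FPKM for Cox6c, 12.17 for Ucp2 and 2.192 for Il1b. These examples were picked after the values were seen, and no test was run on them. The relations do not show how the values of these genes arose.

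The separate profiles were nearly alike, with a lowest correlation of 0.9985 on the log2 scale. The SD of the log2 difference between the WT PBS profiles was 0.131, and across the other pairs it ranged from 0.0947 to 0.139. WT MPTP 1 and KO PBS 1, which differ in both genotype and treatment, had the lowest value. Genes at least 1 log2 unit apart numbered 4 between the WT PBS profiles and between 2 and 21 in the other pairs.

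All 6 profiles had high values for many genes of disease-associated microglia. The list of disease-associated microglia genes had a median of 131 FPKM, with Spp1 at 3192 ± 194, Apoe at 3107 ± 172 and Gpnmb at 3017 ± 142 FPKM (mean ± SD over 6 profiles). The list of homeostatic microglia genes had a median of 1.58 FPKM, and 13 of its 28 members were under 1 FPKM. Among them, Cx3cr1 was at 0.05, P2ry12 at 0.19 and Siglech at 0.03 FPKM, while the macrophage gene Csf1r, at 117 FPKM, was high. These genes were picked after their values were seen. Arg1, an arginase of alternatively activated macrophages, was at 2694 FPKM. Lists of markers of neurons, dopaminergic neurons, oligodendrocytes, their precursors, astrocytes and vessels had medians between 0 and 0.07 FPKM. Some of their members were high, such as Bsg at 265, Trf at 246 and Aldoc at 81.7 FPKM. The medians for lymphocyte, erythroid and granulocyte markers were 0.02, 0.01 and 0.10 FPKM.

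The level of Ppargc1a followed the genotype labels. It was 5.70 and 6.21 FPKM in the WT PBS profiles, 2.72 FPKM in WT MPTP 1, 0.33 and 0.12 FPKM in KO PBS 1 and 2, and 0.42 FPKM in KO MPTP 2. The computed columns held 5.60 in WT PBS 3, 2.83 and 2.95 in WT MPTP 2 and 3, 0.42 in KO PBS 3, and 0.22 and 0.51 FPKM in KO MPTP 1 and 3. Across separate profiles, the mean was 4.88 ± 1.89 FPKM in WT and 0.29 ± 0.15 FPKM in KO (SD, n = 3 each; exact permutation test, two-sided p = 0.10, the smallest that 3 against 3 allows). Ppargc1a was itself a gene off the relations, with departures in WT PBS 3, WT MPTP 2 and KO MPTP 1.

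**Figure D2:**
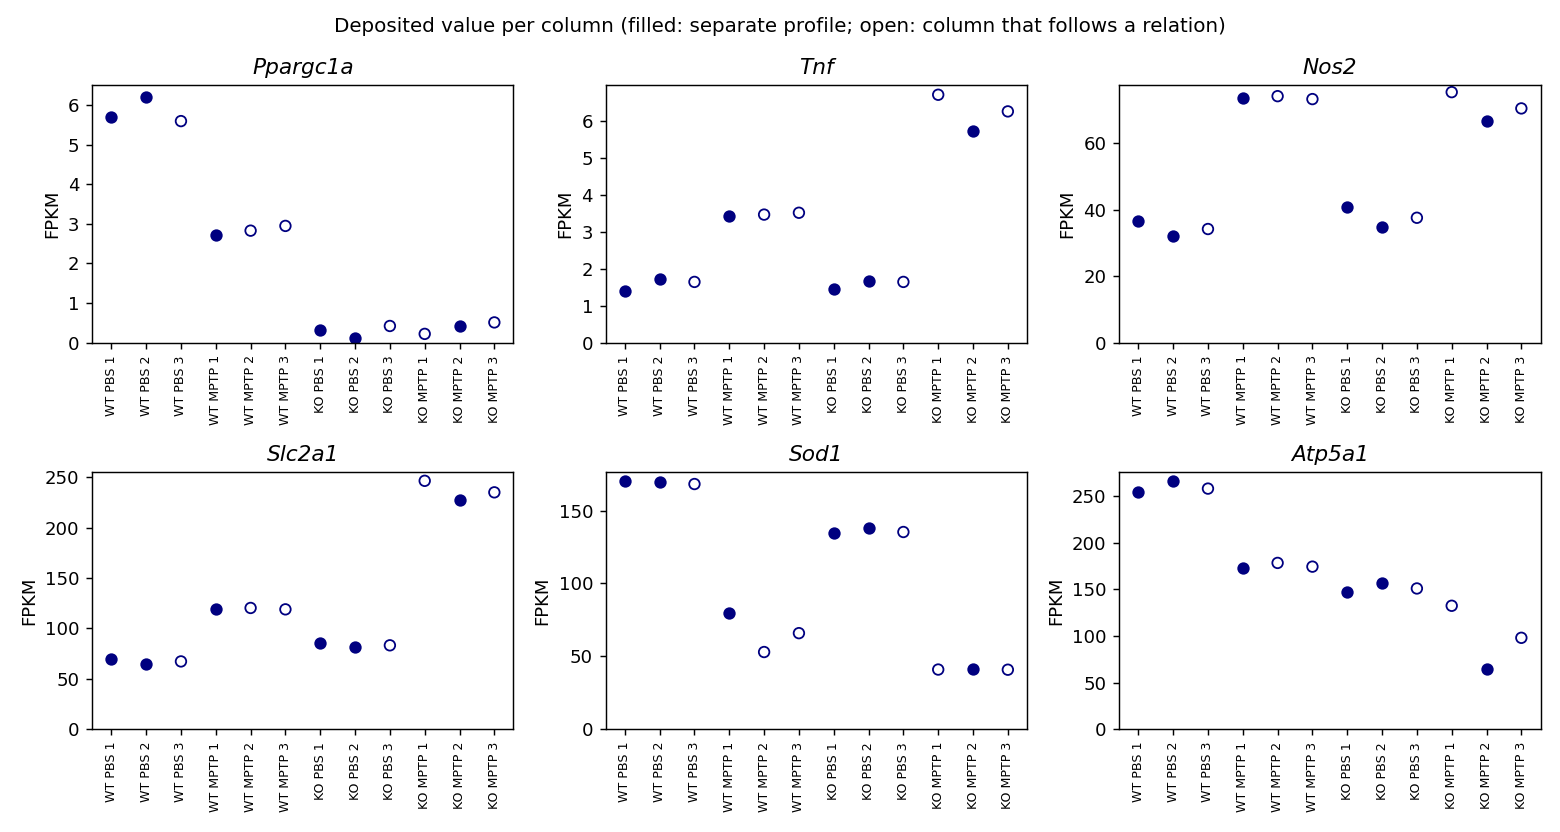
FPKM per deposited column for 6 genes off the relations, with filled points for separate profiles and open points for columns that follow a relation elsewhere in the table. Ppargc1a lies between 2.72 and 6.21 FPKM in WT columns and at 0.51 FPKM or below in KO columns.

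The comparison of WT MPTP with WT PBS addressed the response of control microglia to MPTP-induced neurodegeneration. Among the inflammatory genes that rose, Nos2, the inducible nitric oxide synthase, was 73.5 FPKM in WT MPTP 1 against 36.7 and 32.0 in the WT PBS profiles, a log2 fold change of 1.08 ± 0.09 (SE; limma, adjusted p = 0.00097). The cytokine genes Il1b and Tnf rose by 0.81 and 0.79, Slc2a1 by 0.81 and the calcium-binding protein gene S100a6 by 0.70. Genes of mitochondria and antioxidant defence were among those that fell. Sod1, the cytosolic superoxide dismutase, fell by 1.08 on the log2 scale (adjusted p = 0.000666), Ppargc1a fell by 0.90, Ucp2 fell by 0.75 and Tfam, the mitochondrial transcription factor, fell by 0.70. The transcription factor genes Cebpb, Rela and Nr4a1 fell by 1.09, 1.04 and 0.73, and the nuclear receptor gene Ppard fell by 0.64. The kinase subunit gene Prkag2 fell by 0.70. Aarsd1, Pla2g3 and Rsc1a1, which had no row off the relations, fell by 0.85, 0.70 and 0.70.

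In all, 27 of 10634 genes passed the adjusted threshold in this comparison, 5 higher and 22 lower, and 282 had an unadjusted p under 0.05. With no effect, a share of 0.05 of the 10634 genes would lie there, which is more than 282. Of the 27, 18 were genes off the relations, although only 40 such genes were tested (Fisher's exact test, two-sided p = 1.12e-39). Of 32 tested inflammatory genes, 3 rose and 0 fell (6 rose and 0 fell when adjusted over the list alone), and all 3 were off the relations. The median of the 32 was 0.11 at percentile 100, against −0.03 at percentile 5.49 between the WT PBS profiles. Of 73 oxidative phosphorylation genes, 3 fell (5 adjusted over the list alone): Atp5h, which was not off the relations, Atp5a1 and Ndufs8. That list's median was 0.05 at percentile 10.8, with 56 of the 73 members above 0. Of 21 antioxidant genes, 2 fell, Sod1 and Ucp2 (3 adjusted over the list alone). With the genes off the relations left out before the fit, 4 genes were called, 0 higher and 4 lower. No gene was called without the filter (limma, 1889 of 20425 at an unadjusted p under 0.05), and the 12 columns taken as libraries gave 2149. With the profile under 2 labels counted as KO PBS, 27 genes were called, 6 higher and 21 lower. Leaving out WT PBS 1 from that fit gave 2 higher and 6 lower, of which 6 were among the 27 reported, and leaving out WT PBS 2 gave 11 higher and 12 lower, of which 9 were. Counted as KO MPTP with the values of KO PBS 2, it gave 1 gene higher and 15 lower, and none of the 5 reported rises, all in genes off the relations, was called. With the values deposited as KO MPTP 1 it gave 6 higher and 22 lower, and all 5 rises were called.

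The comparison of KO MPTP with KO PBS addressed the same response in deficient microglia, with 1 profile in each group. Tnf was 5.73 FPKM in KO MPTP 2 against 1.45 in KO PBS 1, a log2 fold change of 1.46 ± 0.13 (SE; limma, adjusted p = 0.0011). Slc2a1 rose by 1.40, the chemokine gene Ccl2 by 1.31, Il1b by 0.85, S100a6 by 0.76 and Nos2 by 0.69. Sod1 fell by 1.68 (adjusted p = 3.59e-05), from 135 to 41.4 FPKM. The respiratory chain genes Atp5a1, Cox6c, Ndufs8 and Cox7b fell by 1.17, 0.87, 0.66 and 0.60. Rela fell by 1.08, Acsl1, which encodes a fatty acid-activating enzyme, fell by 0.83, and the kinase gene Gsk3a fell by 0.69. All of these were genes off the relations. Among the genes with no row off, AI480526, Bzrap1, Cct5, Ptprv and Pde1b rose by 1.02, 0.80, 0.75, 0.73 and 0.72. Cct5, a chaperonin subunit, was 114 FPKM in KO PBS 1 and between 191 and 295 FPKM in the other separate profiles.

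In this comparison 31 genes passed the threshold, 23 higher and 8 lower, and all 8 that fell were genes off the relations. At an unadjusted p under 0.05 (limma) there were 981 of 10634 genes, above a share of 0.05. With TMM rescaling there were 446, below that share. Of 32 inflammatory genes 4 rose and 0 fell, and of 73 oxidative phosphorylation genes 0 rose and 4 fell; when adjusted over the list alone, 4 inflammatory genes rose and 1 fell, and 4 oxidative phosphorylation genes fell. The inflammatory median was 0.08 at percentile 16.8. The oxidative phosphorylation list as a whole did not fall: 66 of the 73 members were above 0. Its median was 0.10 at percentile 98.75, against 0.12 at percentile 100 between the WT PBS profiles. The median of all genes was 0.09 and moved to −0.01 with TMM rescaling, which gave 32 genes higher and 20 lower; quantile normalization gave 3 higher and 5 lower. With the profile that stands under 2 labels counted as KO PBS, 37 genes were called, 28 higher and 9 lower, and with it counted as KO MPTP, 2 were called with the values of KO PBS 2, both higher, and 17 with those of KO MPTP 1, 9 higher and 8 lower. Of these 17, 14 were genes off the relations. With genes off the relations left out 4 genes were called, and without the filter 0 (limma, 2891 of 20425 at an unadjusted p under 0.05).

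The comparison of KO PBS with WT PBS addressed the deficiency without the toxin. Ppargc1a fell by 2.39 ± 0.10 (SE; limma, adjusted p = 3.95e-06). Cebpb fell by 1.51, from 170 and 153 to 55.9 FPKM. Genes of mitochondrial energy metabolism were among the others: Ucp2 fell by 0.85, the ATP synthase genes Atp5a1, Atp5e and Atp5h fell by 0.82, 0.80 and 0.79, and Tfam fell by 0.59. Of 17 tricarboxylic acid cycle genes 2 were lower, Dlat, which fell by 0.53, and Ogdh, which fell by 0.47. Of 19 fatty acid oxidation genes 1, Acadm, fell by 0.49 (adjusted p = 0.0375). Cct5, Aarsd1, Apoc1 and Apoc2 fell by 1.34, 1.09, 1.04 and 0.98. The last 2 encode apolipoproteins. Cct5 was higher in KO PBS 2, the profile left out of the fit, than in KO PBS 1. Atp5h was 225 and 223 FPKM in the WT PBS profiles and between 129 and 144 FPKM in the 4 others, WT MPTP 1 included.

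In this comparison 24 genes passed the threshold, 0 higher and 24 lower, and 8 of them were genes off the relations. Of 73 oxidative phosphorylation genes 3 fell (9 adjusted over the list alone). The median of all genes was −0.06 and moved to 0.0013 with TMM rescaling. The oxidative phosphorylation median of −0.11 lay at percentile 0 among matched random lists, but between the 2 WT PBS profiles the same list had a median of 0.12 at percentile 100. No inflammatory gene was called. The median of that list was 0.01 at percentile 100, with 17 of the 32 members above 0. Between the WT PBS profiles it was −0.03 at percentile 5.49. With the profile under 2 labels counted as KO PBS, 39 genes were called, 1 higher and 38 lower, of which 20 were among the 24 reported. With genes off the relations left out 13 genes were called, and without the filter 0 (limma, 2087 of 20425 at an unadjusted p under 0.05). The 12 columns taken as libraries gave 1321.

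The comparison of KO MPTP with WT MPTP addressed the deficiency under the toxin, with 1 profile in each group. Slc2a1 rose by 0.93 ± 0.09 (SE; limma, adjusted p = 0.00299), from 119 FPKM in WT MPTP 1 to 227 FPKM in KO MPTP 2. Atp5a1, Ppargc1a, Cox6c, Sod1, Acsl1, Cox7b and Gsk3a fell by 1.40, 1.39, 0.98, 0.93, 0.92, 0.90 and 0.84. These 8 were all genes off the relations. AI480526 and the long noncoding RNA Neat1 rose by 0.81 and 0.63, and had no row off.

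In this comparison 11 genes passed the threshold, 4 higher and 7 lower. Of 73 oxidative phosphorylation genes 3 fell (4 adjusted over the list alone), and the list's median of −0.07 lay at percentile 1.93. Of 32 inflammatory genes 0 were called (1 higher and 1 lower adjusted over the list alone). The inflammatory median was −0.05 at percentile 0.54, with 9 of the 32 members above 0. With genes off the relations left out no gene was called (limma, 366 at an unadjusted p under 0.05). With the profile under 2 labels counted as KO MPTP, 0 genes were higher and 2 lower with the values of KO PBS 2, and 1 higher and 4 lower with those of KO MPTP 1, where all 5 were genes off the relations. Slc2a1 was at 0.20 with the former values and 0.99 with the latter. TMM rescaling gave 26 higher and 9 lower, and the 12 columns taken as libraries gave 1539.

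The interaction asked whether the MPTP effect differed between genotypes. It was called for 8 genes, all with a higher MPTP change in KO than in WT: Cct5 at 1.28 ± 0.12 (SE; limma, adjusted p = 0.0106), AI480526 at 1.24, Cebpb at 1.12, Pla2g3 at 1.10 and Aarsd1 at 1.04 among those named by the rule. Of the 8, Cebpb was a gene off the relations. The interaction was 0.66 for Tnf, 0.04 for Il1b, −0.39 for Nos2 and −0.60 for Sod1, none of them called. The inflammatory list had a median interaction of −0.04 at percentile 0.03. Cct5 rests on KO PBS 1, since KO PBS 2 had 191 FPKM and KO MPTP 2 had 193 FPKM. Cebpb was 170 and 153 FPKM in the WT PBS profiles, 75.1 in WT MPTP 1, 55.9 in KO PBS 1 and 57.1 in KO MPTP 2. In the same order, Aarsd1 was 15.5 and 17.0, 8.54, 7.11 and 8.23 FPKM. For these genes the interaction came mainly from the fall in WT. With the profile under 2 labels counted as KO PBS, few of the 8 stayed called. None of the 8 did when WT PBS 1 was also left out, and almost none when WT PBS 2 was left out instead. Without the filter 0 genes were called (limma, 2010 of 20425 at an unadjusted p under 0.05), and TMM rescaling gave 27 higher and 3 lower. Quantile normalization called 1 gene.

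Across the 10634 genes, the MPTP effects in WT and KO had a Pearson r of 0.01 and a Spearman rho of −0.13, and the genotype effects under PBS and MPTP had −0.03 and −0.12; genes are not independent replicates. Of the calls for MPTP, 5 genes were higher in both genotypes (0.011 for independent lists) and 5 lower in both (0.017). Left without the genes off the relations, both numbers were 0, and r was −0.11. For genotype, 4 genes were lower under both treatments (0.016 for independent lists), and 0 without the genes off the relations.

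Calls in the other lists were few and all in genes off the relations. Of 10 tested genes of the PGC-1 family and its partner receptors, Ppargc1a and Ppard fell under MPTP in WT, and Ppargc1a alone fell in KO against WT under either treatment. Of 19 mitochondrial biogenesis factors, Tfam fell under MPTP in WT and in KO against WT under PBS. Of 16 glycolysis genes, Slc2a1 rose under MPTP in both genotypes and in KO against WT under MPTP. Nr4a1, of 27 immediate early and dissociation stress genes, fell under MPTP in WT. That list had a median of −0.14 at percentile 0 in KO against WT under PBS (0 called, 3 lower adjusted over the list alone; limma, 470 of all genes at an unadjusted p under 0.05) and of 0.16 at percentile 99.95 in the interaction, against 0.00 at percentile 44.9 between the WT PBS profiles. S100a6, of 10 monocyte markers, rose under MPTP in both genotypes.

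The remaining lists had no called member. The 19 MHC class I genes had a median of 0.17 at percentile 100 under MPTP in KO (2 higher adjusted over the list alone) and of −0.14 at percentile 0 in KO against WT under PBS; between the WT PBS profiles it was 0.07 at percentile 96.2. The 25 genes of the unfolded protein response had medians of 0.09 and 0.15 under MPTP in WT and KO, and of 0.07 at percentile 98.9 between the WT PBS profiles. Under MPTP in KO the 21 cholesterol synthesis genes had a median of 0.25, at percentile 100, with Fdps at 0.31 ± 0.15 and not called. The same list had a median of 0.20 and percentile 100 between the 2 WT PBS profiles. The 55 ribosomal protein genes had a median of −0.11 at percentile 0 in KO against WT under MPTP, and of 0.11 at percentile 100 between the WT PBS profiles. The disease-associated list had medians of 0.04 and 0.06 under MPTP in WT and KO, with Spp1 at 0.19 ± 0.13 and −0.06 ± 0.16. The homeostatic list had medians of 0.03 and 0.07. The 24 interferon response genes had medians of −0.02 and 0.10, and the 35 cell cycle genes 0.03 and 0.04. Arg1 was at 0.07 ± 0.13 under MPTP in WT and −0.11 ± 0.15 in KO.

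**Figure D3:**
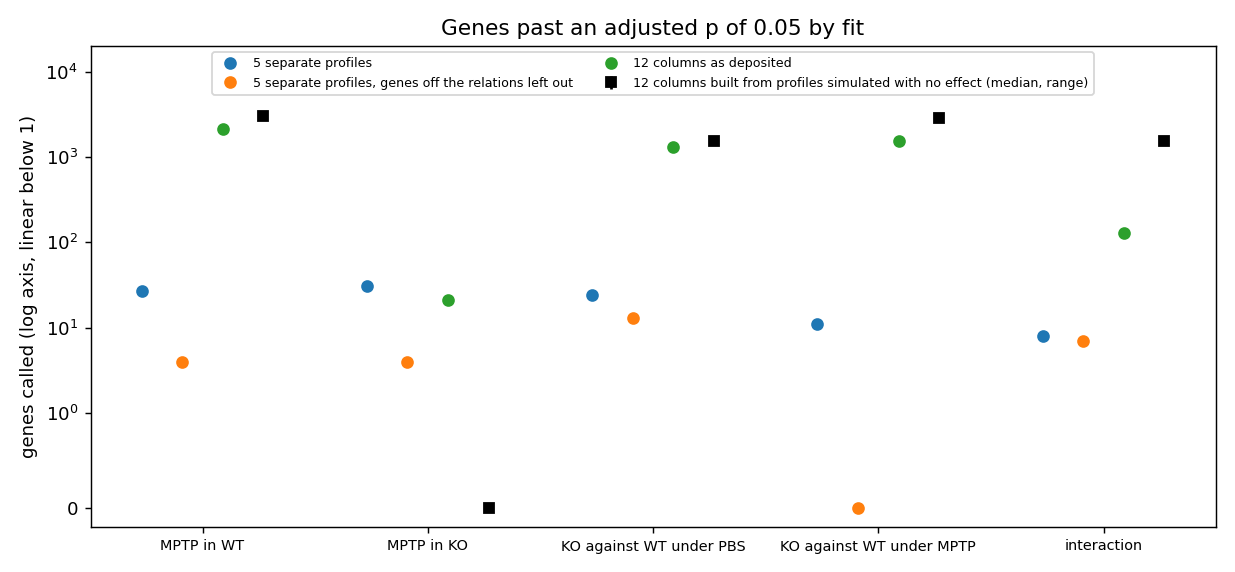
Genes past an adjusted p of 0.05 (log axis, linear below 1) for 5 comparisons in the fit of 5 separate profiles, the same without genes off the relations, the 12 deposited columns, and 12 columns built by the same relations from profiles simulated with no effect (median and range of 20 draws). For MPTP in WT the counts were 27, 4, 2149 and a median of 3008.5.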

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

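The interaction was fixed as a comparison before the data were examined, but its fit of 5 profiles and the tests of explanations in this part were chosen after the results were seen. The interaction of genotype and MPTP was called for 8 genes, and the test of the difference itself is what marks them. The log2 interaction was 1.28 for Cct5, 1.24 for AI480526, 1.12 for Cebpb, 1.10 for Pla2g3 and 1.04 for Aarsd1. Each rests on a single profile in every group except WT PBS, and none was called without the filter on low values. With the profile under 2 labels counted as KO PBS, few of the 8 stayed called. None of the 8 did when WT PBS 1 was also left out, and almost none when WT PBS 2 was left out instead. Signals outside the profiles used in the comparisons were rows of the computed columns that depart from their relations: 1 row of WT PBS 3, 28 of WT MPTP 2 and 46 of KO MPTP 1.

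The first pattern is that 6 of the 12 columns follow fixed arithmetic relations to others. Separately sequenced libraries that agree closely are argued against by the 99.45% or more of rows of at least 10 FPKM within rounding. Between separate columns, at most 0.82% of such rows lay within rounding of their median ratio. That value cannot decide on a normalization applied to every column, which need not make separate libraries proportional. The 99.45% or more within rounding argue against a scaling of each column by itself, since it would leave the scatter between separate libraries in place. What remains open is how the computed columns came to be deposited, which no test on the table can show, and which treatment the profile under KO PBS 2 and KO MPTP 1 had. No biological explanation was tested.

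The second pattern is that genes off the relations carry many of the calls. Departures that fall on rows by chance, whatever the gene, are argued against by their share in the gene lists (Fisher's exact test, p = 5.73e-33). Many of these genes were called between the separate profiles; whether treatment or genotype is behind that stays open, as does how the departing values arose. The differences that rest on these genes, those in Ppargc1a, Tnf, Nos2, Sod1 and the respiratory chain among them, therefore have no replicate support in this table beyond the separate profiles.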

How the results depend on the processing

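The fit of 5 profiles, the fits that use the shared profile (those with a profile left out among them), the fits without genes off the relations, the fit of each table row and the role of the 12 columns as an alternative were chosen after the result was seen. Counts of called genes are given in the order MPTP in WT, MPTP in KO, KO against WT under PBS, KO against WT under MPTP and interaction, where the reported counts were 27, 31, 24, 11 and 8. No gene was called in any of them without the filter on low values, or with each row of the table tested by itself (650, 1408, 927, 1014 and 1057 at an unadjusted p under 0.05). Quantile normalization gave 16, 8, 9, 7 and 1. TMM rescaling gave 44, 52, 33, 35 and 30. A filter at 5 FPKM gave 51 for MPTP in KO, 19 for KO against WT under MPTP and 18 for the interaction. Without the variance trend the counts were 20 for MPTP in KO and 5 for the interaction. At a threshold of 0.1 they were 56 for MPTP in KO, 17 for KO against WT under MPTP and 20 for the interaction. Leaving out genes off the relations gave 4, 4, 13, 0 and 7. Counting the profile under 2 labels as KO PBS gave 27, 37, 39, 13 and 4, and as KO MPTP 16, 2, 23, 2 and 6 with the values of KO PBS 2, or 28, 17, 29, 5 and 5 with those of KO MPTP 1. The pseudocounts kept each count within 1.5 times, and the fit on only the groups compared gave 27 for MPTP in WT and 24 for KO against WT under PBS. The cause was not tested.

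The 12 columns as deposited, the fit that the design fixed before the data were examined, gave 2149, 21, 1321, 1539 and 127. With the replicate number as a block they gave 3841, 3303, 3025, 3138 and 1043, and with array weights 2495, 9103, 905, 8870 and 1051. Only WT PBS and KO PBS hold separate profiles under the same numbers, 1 and 2; their deviations had a correlation of 0.227 over 10634 genes, too few pairs to treat the samples as paired. With 5 profiles the block, array weights and leaving out a WT PBS profile could not be fitted or leave no residual degree of freedom. With the shared profile counted as KO PBS, leaving out WT PBS 1, WT PBS 2 or KO PBS 1 in turn gave 8 to 27, 11 to 13, 16 to 32, 7 to 11 and 1 to 4. WT MPTP 1 and KO MPTP 2 are the sole profiles of their groups.

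The correlation of MPTP effects between genotypes was between −0.10 and 0.10 with either WT PBS profile left out. That of genotype effects was −0.03, and −0.0606 with a pseudocount of 0.1, −0.11 without genes off the relations, 0.25 with the 12 columns, with or without the block, and −0.04 to −0.01 with either WT PBS profile left out. The log2 difference in Ppargc1a between KO and WT was −2.136, and −2.121 after TMM rescaling. Among named genes, 6 not called in KO against WT under MPTP took the other sign and a call with array weights on the 12 columns: Bst2 at −0.056, Ifi204 at −0.053, Aldoc at −0.096, Flt1 at −0.076, Cxcr2 at −0.072 and Cd28 at −0.065. Of 125 list medians, 58 took the other sign with quantile normalization and 50 with TMM rescaling. The set tests planned for the lists (camera, fry) were not run.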

Other observations

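The tests of explanations and the simulation in this part were chosen after the values had been seen, while the fit of 12 columns was fixed before. Genes of resting microglia lay near the floor in every separate profile: the homeostatic list had a median of 1.58 FPKM. The disease-associated list had a median of 131.19 FPKM. That value cannot decide on low depth, because FPKM is scaled by all mapped fragments and the read depth is unknown. Cells of other brain types as a large part of the sample are argued against by medians of at most 0.07 FPKM for their markers. Of the markers in the deposited data, 7 of 12 for neurons, 11 of 13 for oligodendrocytes, 11 of 15 for astrocytes and 12 of 15 for vessels were under 1 FPKM. Some others were high, such as Bsg at 265, Trf at 246, Flt1 at 86.9 and Aldoc at 81.7 FPKM. A small part of such cells therefore stays open. Macrophages of the brain borders or from blood are a candidate explanation that cannot be told apart from an altered state of microglia: the border list had a median of 11.81 FPKM, with Pf4 at 191 and Mrc1 at 158 FPKM but Lyve1 at 0.12 FPKM, and the monocyte list 0.72 FPKM, with Ccr2 at 0.02 FPKM. Macrophages in several states share Pf4 and Mrc1, and the sort, whose markers are not given in the sources used here, may have removed such cells or kept them. The 35 cell cycle genes had a median of 14.84 FPKM, with 0 of them under 1 FPKM. Whether the cells were dividing was not tested.

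Profiles simulated with no effect show what the computed columns do to a test. When 12 columns were built from 6 such profiles by the relations in the table, limma called a median of 3008.5 genes for MPTP in WT, 1528 for KO against WT under PBS, 2893 for KO against WT under MPTP, 1518.5 for the interaction and 0 for MPTP in KO, over 20 draws of 10634 genes. The deposited columns gave 2149, 1321, 1539, 127 and 21. The deposited columns exceeded the simulated counts only for MPTP in KO, and all 21 genes called there were genes off the relations. In rows that follow the relations, KO PBS and KO MPTP share a profile, and the simulation called 0 genes there in every draw. Because of that shared profile, the place of the 21 calls cannot decide whether other genes differed between these groups.

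1 value stood apart without being part of a comparison. A row of Prkag2, a subunit gene of the energy-sensing kinase AMPK, was 122 FPKM in KO PBS 2 and 71.8 FPKM in KO PBS 3, and between 12.5 and 23.6 FPKM in the other columns, KO MPTP 1 included.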
